A study of Mus musculus with 11 samples.

How the data were processed

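Total RNA was sequenced from HT22 mouse hippocampal cells and from the stably transfected derivative HT22[TR/TO-Klf9]. Per the labels' protocols, cells were plated at about 250000 per well of 6-well plates in medium with 10% serum and, 24 hours later, given 0.5 µg/ml doxycycline or DMSO vehicle for 8 hours; libraries were oligo-dT primed. The deposited table holds whole-number read counts per RefSeq transcript for all 11 samples, with no normalization, as its values show; columns not used numbered 0. Per the submitters' processing notes, CASAVA, FastQC, Bowtie and DESeq were used with build mm8; the counting program, strand setting, annotation release and tool versions are not given in the sources used here. The RefSeq names were read with a GRCm38 gene table, used for symbols, chromosome and neighbour order only, so no coordinates are given.

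Of 33815 rows, 32923 distinct accessions, 32500 paired with a gene symbol and 423 did not; these 423 held 0.739% to 0.773% of the counts per library and were tested under their own identifier. Transcripts of a gene share reads in the table: of 4835 genes with more than 1 row, 2662 had identical rows. The row with the highest mean count was kept for each gene, leaving 24143 genes, since summing would count a read several times. Total counts after this step ranged from 10302431 to 18902784, and CPM are counts scaled to library size after TMM.

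Samples were grouped by the titles in the labels. TR/TO-Klf9 vehicle 3 and TR/TO-Klf9 doxycycline 1 held the same count in every row. Because the labels conflict, the library could not be assigned and both columns were left out, which departs from the design fixed before the data were examined (all 11 columns). Fits with the library under both labels, as vehicle or as doxycycline are given as alternatives chosen after the data were seen, as are removing a transcript length trend, summing rows, and fits within the TR/TO-Klf9 line with those choices. The pooled fit had 9 libraries and 5 residual degrees of freedom, and the only remaining TR/TO-Klf9 doxycycline library was assumed to vary like the others.

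Genes were filtered with filterByExpr by group, scaled by TMM and tested with edgeR 4.0.16 (glmQLFit with robust estimation, glmQLFTest; 4 group means) in R 4.3.3. Adjusted p-values follow Benjamini-Hochberg over the 13536 genes tested, with a threshold of 0.05; SE is the log2 fold change over the root of its F statistic. The common dispersion was 0.00229, a coefficient of variation of 4.78%. Comparisons were doxycycline against vehicle in each line, the difference of these effects, and the lines under vehicle. Alternatives fixed beforehand were DESeq2 1.42.0, limma-voom 3.58.1, RLE scaling, no filter or a stricter filter (1 CPM in 5 libraries), the replicate number as a block shared by lines or within each line, only the groups compared, and leaving out each library in turn.

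Gene lists, 36 in all, were fixed before the data were examined; 33 with at least 5 tested members were tested with camera (preset correlation 0.01, adjusted over lists), and also with an estimated correlation and with fry. Mitochondrially encoded genes matched no row, and 2 marker lists had fewer than 5 tested members. Named genes followed a rule fixed beforehand: Klf9; per comparison the 10 largest rises and 10 largest falls among genes past the threshold, with at least 5 CPM in the higher group, separated groups and no clone name; up to 4 members per list past the threshold; and KLF or SP genes past it. Some genes that met this rule are not reported here.

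Transcript lengths came from GENCODE M21 transcripts matched by RefSeq accession, for 97.9% of tested genes; the trend of each library on log2 length was fitted by loess with a span of 0.4 and entered as an offset. The test was tried on simulated counts for 13536 genes with 200 changed, drawn from genes averaging at least 5 CPM. For doxycycline in the TR/TO-Klf9 line 83.6%, 98.5% and 100% of genes changed 1.5-, 2- and 4-fold were recovered with 8 false calls, for the parent line 98.5%, 98.5% and 100% with 15, for the difference 86.6%, 98.5% and 100% with 7, and for the lines 98.5%, 98.5% and 100% with 2. A simulated length trend with no changed gene gave 810 calls, and 0 with the correction. Simulations assume equal spread in every group. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 did the remaining steps.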

Results

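RNA sequencing counts were examined from HT22 cells, an SV40-immortalized mouse hippocampal neuronal line, and from a derivative, TR/TO-Klf9, that carries a tetracycline repressor and a Klf9 cassette that doxycycline switches on. Klf9 is a zinc finger transcription factor of the KLF family. Each line was treated with doxycycline at 0.5 µg/ml or with vehicle for 8 hours, and the question was which genes respond to Klf9 induction. The labels named 11 samples: 3 parent vehicle, 3 parent doxycycline, 3 TR/TO-Klf9 vehicle and 2 TR/TO-Klf9 doxycycline. TR/TO-Klf9 vehicle 3 and TR/TO-Klf9 doxycycline 1 held identical counts in every row, so 1 library stood under opposite labels and was left out of both groups. The comparisons therefore used 9 libraries, with 2 TR/TO-Klf9 vehicle libraries and 1 TR/TO-Klf9 doxycycline library. Total counts ran from 10302431 to 18902784 per library, with 12383212 in the TR/TO-Klf9 doxycycline library. The labels do not say whether replicates were separate cultures, so p-values measure only the spread between these samples.

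Klf9 itself was reported first, since it checks the labels. Klf9 (NM_010638, on chromosome 19) stood at 38.54 ± 2.68 library-size-scaled counts (CPM) in parent vehicle cells (SD, n = 3) and 38.67 ± 0.79 in parent doxycycline cells (SD, n = 3). It stood at 46.37 ± 3.28 in TR/TO-Klf9 vehicle cells (SD, n = 2) and at 101.44 in the TR/TO-Klf9 doxycycline library, a 2.19-fold rise (log2 1.13 ± 0.08 SE, adjusted p = 7.45e-07). The identical library held 537 Klf9 counts, 45.91 CPM, inside the range of the other TR/TO-Klf9 vehicle libraries. Without doxycycline, Klf9 was 1.19-fold higher in TR/TO-Klf9 than in parent cells (log2 0.26 ± 0.07 SE, adjusted p = 0.00865). Reads from the endogenous gene and from the cassette were not told apart here.

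**Figure D1:**
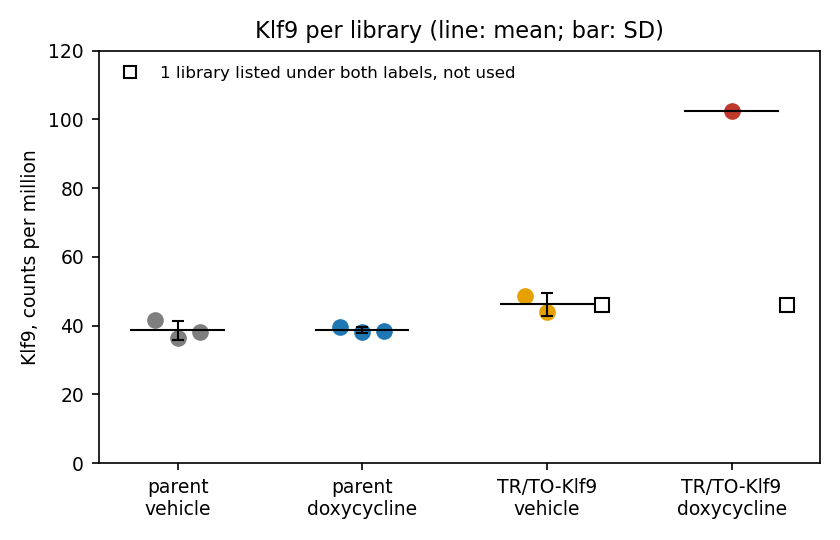
Klf9 in CPM (y axis) for each library of the 4 groups (x axis), with the mean as a line and the SD as a bar where a group has more than 1 library; open squares mark the library listed under both labels. The doxycycline library of the TR/TO-Klf9 line lies at 102.42 and every other library between 36.28 and 48.53, on the scale of all 11 columns.

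In TR/TO-Klf9 cells, the falls after doxycycline were larger than the rises. Zbed6, a transcriptional repressor encoded inside Zc3h11a, fell from 109.69 ± 12.87 CPM (SD, n = 2) to 30.95 (log2 −1.83 ± 0.10 SE, adjusted p = 5.65e-08). Celf3, an RNA-binding splicing regulator, fell by 1.86 on the log2 scale, and Gpr161, a receptor that restrains hedgehog signalling, by 1.81. The zinc finger gene Zfp369 fell by 1.69, the ubiquitin ligase genes Trim56 and Cbl by 1.65 and 1.54, and Wdfy2 by 1.44. Pde6b, Rptoros and Zbtb37 completed the 10 largest falls, between −1.64 and −1.45. Klf9 led the rises, followed by the homeobox gene Nkx6-2 (log2 0.93 ± 0.21 SE), Arxes1 (0.92 ± 0.18), the lysosome positioning gene Borcs5 (0.89 ± 0.19) and Enpp3 (0.88 ± 0.26). Ptgdr2, Ces1g, Tmem255a, Sat2 and Syce2 rose by 0.77 to 0.86, and with the length trend below removed Ces1g and Sat2 did not pass but stayed at 0.79 and 0.68. Nkx6-2, Ptgdr2, Tmem255a, Syce2, Celf3, Zbed6, Gpr161 and Rptoros overlap another tested gene, and with no strand given in the sources used here their reads may include the partner's.

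Across the 13536 genes tested, 2410 passed an adjusted p of 0.05, 872 up and 1538 down, and 47 up and 353 down changed at least 1.5-fold. DESeq2 called 1319 genes, 244 up and 1075 down, with 15 up and 276 down at 1.5-fold. Without TR/TO-Klf9 vehicle 2 the 1.5-fold counts were 167 up and 638 down. The lone doxycycline library was assumed to vary like the others. This assumption carried much of the count. TR/TO-Klf9 vehicle 1 and vehicle 2 themselves differed, with a median absolute log2 ratio of 0.111 for genes above 8 CPM. The doxycycline library differed from them by 0.171 and 0.162 on the same measure. With only the 3 libraries of this line in the fit 73 genes passed (1 up, 72 down). With the identical library under both labels no gene passed (0 by edgeR, with 1480 at an unadjusted p under 0.05), but that fit puts the same counts in both groups. With the library as doxycycline only the count was also 0, and with it as vehicle only the count stayed within 1.5 times of 2410. Folds also went with transcript length, as genes that fell had a median transcript of 5047 nt and genes that rose 1855 nt. With that trend removed 1483 genes passed, 1146 of them called before in the same direction. A set of 68 genes passed with the pooled fit, with the length trend removed and with only this line in the fit: Klf9 rose and 67 fell, among them Zbed6, Celf3, Gpr161, Zfp369, Trim56, Cbl, Wdfy2, Klf13, Acaca and Map1b. Rest, the repressor of neuronal genes, was also among the 67 (log2 −1.06 ± 0.09 SE) and was singled out after its value was seen.

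**Figure D2:**
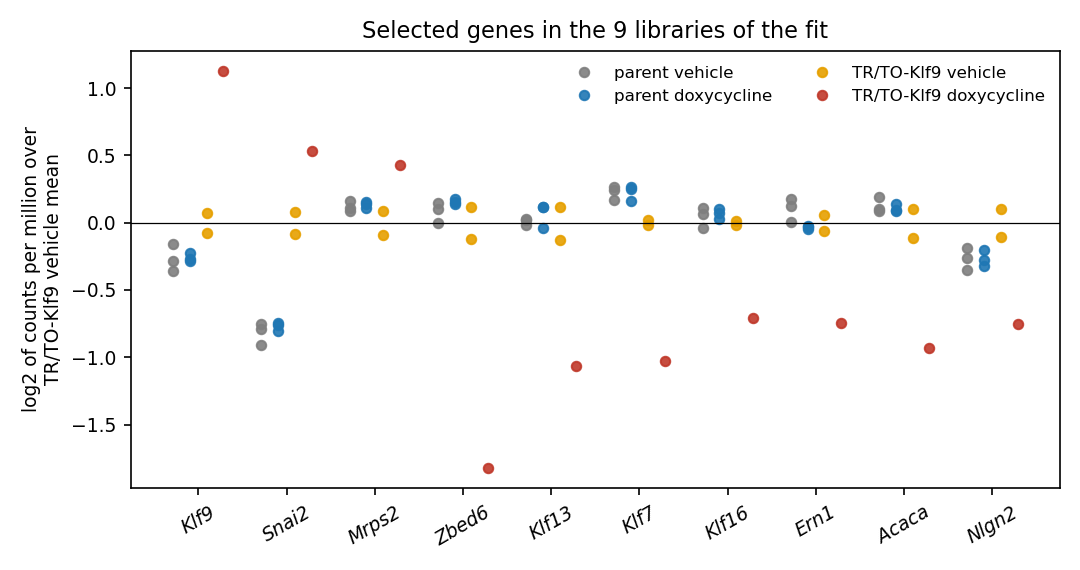
CPM of 10 genes in each of the 9 libraries of the fit, as the log2 ratio (y axis) to the mean of the 2 TR/TO-Klf9 vehicle libraries; each point is 1 library and colours give the group. The TR/TO-Klf9 doxycycline library lies outside the range of both vehicle libraries of its line for each gene shown, above it for Klf9, Snai2 and Mrps2 and below it for the other genes. This holds for all 2410 called genes, from which the genes shown were taken, so it is no added support.

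Other members of the KLF and SP family, zinc finger factors that bind GC-rich promoters, were lower in part. Of 15 measured members other than Klf9, 7 fell and none rose (8 fell adjusted over the list alone), with a median log2 change of −0.39 and an adjusted p of 8.65e-04 by camera. That adjusted p was 0.302 with an estimated correlation and 0.00279 with the length trend removed. Klf13, the closest relative of Klf9, fell by 1.07 ± 0.11 (SE, adjusted p = 1.48e-05), Klf7 by 1.03 ± 0.14 and Klf16 by 0.71 ± 0.09, and these also passed with the length trend removed. Klf11 fell by 0.61, Klf5 by 0.54, Sp1 by 0.39 and Klf3 by 0.26, and these did not pass once the trend was removed. Klf11 and Klf5 then stayed about as low (−0.54 and −0.51), while Sp1 and Klf3 moved to −0.15 and −0.13. The estimated correlation of the list was 0.001, under the preset 0.01, so the loss of its call by camera does not reflect a larger correlation.

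Some genes of short transcripts for ribosomes and the respiratory chain rose modestly, and their lists passed by camera only with the preset correlation. Of 30 mitochondrial ribosome genes, 15 rose and none fell (17 rose adjusted over the list alone), with a median of 0.23 (adjusted p = 6.84e-08 by camera, 0.437 with an estimated correlation). Mrps2 and Mrpl15 rose by 0.43, Mrps22 by 0.42 and Mrpl4 by 0.41. Of 42 nuclear respiratory chain subunits 5 rose (1 adjusted over the list alone; adjusted p = 5.37e-05, or 0.775 with an estimated correlation), with Ndufs8 at 0.36 ± 0.07 (SE) and Atp5g1 at 0.48 ± 0.15. Of 48 cytoplasmic ribosomal protein genes 7 rose (7 adjusted over the list alone; adjusted p = 9.79e-05, or 0.437 with an estimated correlation), with Rpl37 at 0.37 ± 0.10 and Rpl15 at 0.33 ± 0.10; many have processed pseudogenes that share reads. Of 35 G2/M genes 4 rose (2 adjusted over the list alone; adjusted p = 0.0162, or 0.775 with an estimated correlation), namely Cdc25c (0.47 ± 0.11), Ccnb2 (0.43 ± 0.12), Plk1 (0.35 ± 0.11) and Ccnb1 (0.32 ± 0.10). In TR/TO-Klf9 vehicle 1, 6 G2/M genes were lower than in vehicle 2 and none higher (list median −0.13), which lowers the vehicle mean. With the length trend removed the adjusted p was 1.07e-04 for the mitochondrial ribosome, 0.234 for the respiratory chain, 0.553 for cytoplasmic ribosomal proteins and 0.00265 for G2/M. The genes past the threshold were then 8 up and 1 down, 1 up, 0 and 1 up, in that order, and several named genes were no longer among them. Of these Plk1, Ccnb1, Ccnb2 and Rpl15 stayed at 0.30, 0.29, 0.34 and 0.26, while Ndufs8 and Rpl37 dropped to 0.21 and 0.22. The G2/M list did not pass by camera for the difference of the doxycycline effects between lines. By camera it also passed upward in the parent line, so its rise is not set apart from doxycycline itself.

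None of the other 28 lists passed by camera, although single members changed, and 1, the fibroblast and mesenchymal list, passed upward with the length trend removed (adjusted p = 0.0277). The fry test passed 4 of them, all downward: ion channels and calcium handling (adjusted p = 0.0139), axon and neurite growth (0.0211), endothelial markers (0.0211), and glucocorticoid and thyroid hormone response (0.0276). Respiratory chain and G2/M genes, whose lists passed by camera, did not pass by fry. The 4 falls of the ion channel list became 0 falls and 2 rises with the length trend removed. In the clock list, 4 of 17 genes fell, among them Per3 (−0.56 ± 0.13 SE), Per1 (−0.50 ± 0.12), Nr1d2 (−0.63 ± 0.16) and Clock (−0.22 ± 0.07; 0.09 with the length trend removed). Of the clock genes 3 were higher and none lower in TR/TO-Klf9 vehicle 1 than in vehicle 2 (median 0.16), and 3 fell with the length trend removed. In cholesterol synthesis, 7 of 22 genes fell and 2 rose, with Insig1, the retention factor of SREBP, at −0.52 ± 0.09, the transcription factor Srebf2 at −0.36 ± 0.09 and Fdps at −0.53 ± 0.13. With the length trend removed 3 fell and none rose, and Srebf2 did not pass (−0.24, adjusted p = 0.115). In fatty acid synthesis, 3 of 16 fell, led by Acaca, the acetyl-CoA carboxylase gene, at −0.93 ± 0.10. With the length trend removed 3 fell and 2 rose, and Acaca stood at −0.65. Of 35 axon and neurite growth genes 9 fell and 2 rose, with Map1b at −0.80 ± 0.10, Limk1 at −0.66 ± 0.13 and Plxna1 at −0.60 ± 0.10. With the length trend removed 2 fell and 1 rose, Map1b stood at −0.43 and Plxna1 did not pass (−0.31). Of 21 synaptic genes 2 fell, among them Nlgn2 at −0.75 ± 0.09. Of 20 chromatin corepressor genes 6 fell and 1 rose, with Rcor1 at −0.40 ± 0.08 and Sin3a at −0.27 ± 0.07. With the length trend removed 1 fell and 1 rose, and Sin3a did not pass (−0.15, adjusted p = 0.152). Among cell cycle regulators E2f3 fell by 0.49 ± 0.08 and Cdkn2d rose by 0.55 ± 0.12, and in the unfolded protein response Ern1, the IRE1 sensor, fell by 0.75 ± 0.09. Of 21 fibroblast and mesenchymal genes 3 rose and 1 fell, with Snai2 at 0.53 ± 0.09, Twist1 at 0.50 ± 0.10 and Col5a1 at −0.36 ± 0.09, the last at −0.10 and not passing with the length trend removed. No astrocyte or endothelial marker passed, and 1 of 5 neuron markers, Elavl3, fell by 1.46 ± 0.37. No gene of the oxidative stress list passed and 1 of the heat shock list, Hspd1, fell by 0.25 ± 0.08. In TR/TO-Klf9 vehicle 1, 19 of the 28 and 12 of the 18 genes on these lists were higher than in vehicle 2.

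**Figure D3:**
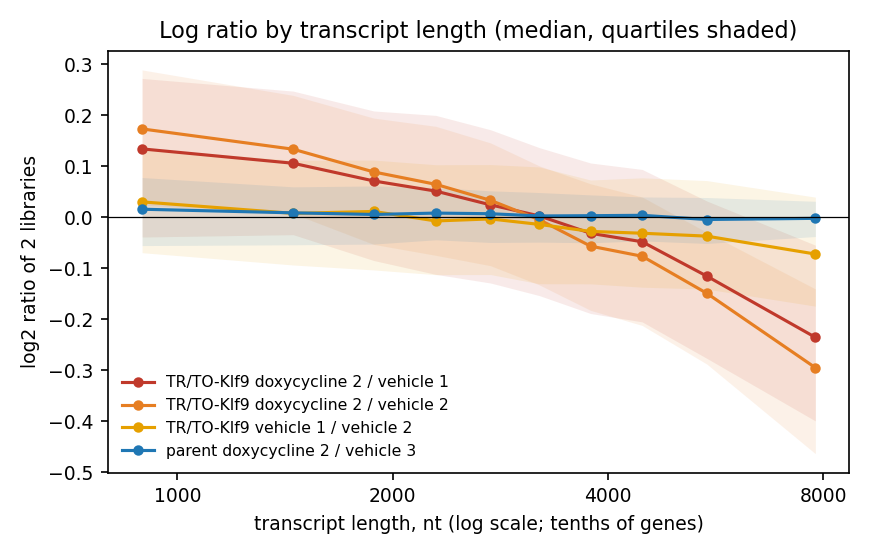
Median log2 ratio between pairs of libraries (y axis) in equal groups of genes ordered by transcript length in nt (x axis, log scale), with the quartiles shaded, for genes averaging over 8 CPM. The TR/TO-Klf9 doxycycline library falls against both vehicle libraries as transcripts lengthen, the 2 vehicle libraries differ less with length, and a parent pair stays near 0.

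Doxycycline alone left the parent line without a detectable change. No gene passed in parent cells (0 by edgeR, 0 by DESeq2 and 0 by limma-voom), against 293 of 13536 at an unadjusted p under 0.05 by edgeR, 40 by DESeq2 and 305 by limma-voom. Klf9 changed by −0.01 ± 0.07 (log2, SE). The smallest p-values belonged to the transcription factor gene Gata2 (28.35 ± 1.54 CPM in vehicle and 23.59 ± 1.19 in doxycycline, SD, n = 3 each, adjusted p = 1.0 in the edgeR fit) and to Ceacam2 (3.12 ± 0.09 and 4.67 ± 0.41, adjusted p = 1.0). In simulated data of this design, 98.5% of genes changed 1.5-fold were recovered, all of them drawn from genes averaging at least 5 CPM. By camera, 4 lists rose, each with 0 members past the threshold: integrated stress response (median 0.07, adjusted p = 7.61e-05; Phgdh 0.12 ± 0.06 SE), G2/M (median 0.04, adjusted p = 0.00438; Top2a 0.10 ± 0.07), respiratory chain (median 0.05, adjusted p = 0.00438; Cox7a2 0.15 ± 0.07) and fibroblast genes (median 0.04, adjusted p = 0.00438; Vim 0.13 ± 0.09). The adjusted p of each was 0.922 with an estimated correlation, and 1 of the 4 passed with no filter on low counts. Parent doxycycline 2 and 3 differed by less than sampling noise (chi-square per degree of freedom 0.952, p = 1.0). They were kept as separate samples because pairs of opposite treatment lay almost as close (1.048 at the lowest), and no gene passed with either left out.

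Set against the parent line, the doxycycline response of TR/TO-Klf9 cells differed at several genes named above. Sat2 responded by 1.198 ± 0.31 more on the log2 scale (SE) and Klf9 by 1.14 ± 0.11 (adjusted p = 1.01e-05), followed by Tmem255a (1.11 ± 0.29), Nkx6-2 (1.06 ± 0.27), Enpp3 (1.03 ± 0.31) and Borcs5 (1.02 ± 0.24). Part of these came from uncalled changes in the parent line, −0.38 ± 0.19 for Sat2 and −0.29 ± 0.18 for Tmem255a, and with the length trend removed Sat2, Tmem255a, Enpp3 and Borcs5 did not pass, at 1.06, 1.03, 1.10 and 0.87. Zbed6 responded by −1.90 ± 0.12 (adjusted p = 2.47e-07), Gpr161 by −1.83 ± 0.20, Celf3 by −1.77 ± 0.28, Zfp369 by −1.70 ± 0.18, Trim56 by −1.65 ± 0.17 and Cbl by −1.49 ± 0.17. Klf13 responded by −1.12 ± 0.13, Klf7 by −1.03 ± 0.17, Klf16 by −0.73 ± 0.10 and Sp1 by −0.40 ± 0.11. These were 4 of 15 genes in the KLF and SP family (7 adjusted over the list alone). The camera adjusted p of that list was 8.78e-04, and 0.342 with an estimated correlation, which was 0.008 and so under the preset 0.01. Mitochondrial ribosome genes differed upward, 7 of 30 (13 up and 1 down adjusted over the list alone; adjusted p = 1.69e-06), and respiratory chain and cytoplasmic ribosomal genes also passed by camera, but none with an estimated correlation (adjusted p of 0.527, 0.884 and 0.527). In all, 1309 genes passed, 372 up and 937 down; DESeq2 called 716, 47 up and 669 down. The count was 586 with the length trend removed. It was 0 with the identical library under both labels (0 by edgeR, with 654 at an unadjusted p under 0.05). With that library as vehicle only the count stayed within 1.5 times of 1309. It was 714, 621, 632 and 571 without parent vehicle 3 or parent doxycycline 1, 2 or 3, while it was 2046 and 2910 without TR/TO-Klf9 vehicle 1 or 2.

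Under vehicle, the lines differed far more than either responded to doxycycline. Genes of the NF-kB and inflammatory response were lower in TR/TO-Klf9 cells: 14 of 17 fell and none rose (14 fell and 1 rose adjusted over the list alone), with a median of −0.60 (camera adjusted p = 1.95e-17, and adjusted p = 0.00688 with an estimated correlation). The chemokine genes Cxcl1 and Ccl2 stood at −2.96 ± 0.10 and −1.76 ± 0.08 on the log2 scale, and the NF-kB inhibitors Tnfaip3 and Nfkbia stood at −1.09 ± 0.07 and −0.92 ± 0.06 (SE). Fibroblast and mesenchymal marker genes were higher, 10 of 21 with 2 lower (10 higher and 3 lower adjusted over the list alone). Acta2 stood at 1.74 ± 0.06, Postn at 1.36 ± 0.09, Pdgfrb at 0.82 ± 0.08 and Snai2 at 0.81 ± 0.07. The camera adjusted p of the list was 8.78e-05, or 0.843 with an estimated correlation. Of 20 TGF-beta and SMAD target genes 11 were higher and 3 lower (12 and 3 adjusted over the list alone). The camera adjusted p was 0.0286, or 0.386 with an estimated correlation, which was −0.004 and so under the preset 0.01. Pmepa1 stood at 0.60 ± 0.06, the receptor gene Tgfbr2 at 0.48 ± 0.06 and Tgfbr1 at −0.49 ± 0.07. Cytoplasmic ribosomal protein genes were lower, 19 of 48 with 2 higher (24 and 2 adjusted over the list alone; adjusted p = 0.0286, or 0.843 with an estimated correlation), among them Rps12 at −0.73 ± 0.06 and Rpl32 at −0.45 ± 0.06, which host or overlap small nucleolar RNA genes. G2/M genes were also lower, 14 of 35 (14 adjusted over the list alone; adjusted p = 0.0493, or 0.877 with an estimated correlation), among them Kif23 and Cdk1 at −0.33 and Cenpf at −0.34. The adjusted p of this list was 0.0593 with the length trend removed, and its median of −0.13 equalled that of TR/TO-Klf9 vehicle 1 against vehicle 2.

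The largest single differences were genes close to silent in 1 of the lines. Gas7 stood at 39.30 ± 1.97 CPM in parent vehicle cells (SD, n = 3) and 0.23 ± 0.12 in TR/TO-Klf9 vehicle cells (SD, n = 2). The axon guidance gene Sema3a fell from 22.57 ± 0.87 to 0.19 ± 0.15 and Phf19 from 17.57 ± 1.80 to 0.15 ± 0.01. The matrix proteoglycan gene Dcn held 620 counts in parent and 2 in TR/TO-Klf9 vehicle libraries, a ratio of 196 (95% counting interval 54.1 to 1620). Zfhx4 held 879 and 2 counts (ratio 278, interval 76.7 to 2300), Serpina3h 729 and 2 (231, 63.6 to 1910), Plxna4 343 and 2 (108, 29.8 to 899), Tnfrsf21 333 and 1 (211, 37.5 to 8340) and Galnt17 332 and 1 (210, 37.4 to 8320); these intervals cover counting error only. Higher in TR/TO-Klf9 cells were the cytokine gene Tnfsf18 (0.10 ± 0.13 against 7.87 ± 0.96 CPM), the cilium gene Hydin (log2 3.18 ± 0.31 SE), the actin bundling gene Lcp1 (3.16 ± 0.33), Klhl30, Il2rg, the neprilysin gene Mme, the receptor gene Csf1r (2.75 ± 0.20), Adamts20 and Serpinb9b, the last 6 by 2.63 to 3.14. Csf1r is a macrophage marker, and only 4 of that list's genes were measured, too few for its test.

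The remaining lists did not pass between the lines by camera, yet held large single differences. In the immediate early list Dusp6 was at −1.19 ± 0.07 and Dusp1 at 1.08 ± 0.10, in the glycolysis list Hk2 at −0.71 ± 0.06 and Pfkl at −0.73 ± 0.06, and in the calcium list the channel genes Cacna1c and Cacna1a were at −5.45 ± 0.32 and −0.90 ± 0.08. Ncam1 (1.42 ± 0.06) and Nrp1 (0.84 ± 0.06) were higher and the neuronal tubulin gene Tubb3 was lower (−1.19 ± 0.10). Of 17 clock genes 8 were higher and 1 lower, with Per1 at 0.53 ± 0.09 and Arntl at −0.40 ± 0.07, and 3 of the list were also higher in TR/TO-Klf9 vehicle 1 than in vehicle 2. Of the other KLF genes Klf4, Klf10 and Klf3 were lower, at −0.54 ± 0.09, −0.32 ± 0.06 and −0.28 ± 0.06. In all, 5264 of 13536 genes passed, 2548 higher and 2716 lower, with 1582 at least 1.5-fold apart; DESeq2 called 3850. The differences ran in blocks along the genome: on chromosome 16, 300 genes were higher and 15 lower, and on chromosome 10, 15 were higher and 403 lower. Whether the genes and lists named for the line difference differ beyond the shift of their chromosome was not tested.

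**Figure D4:**
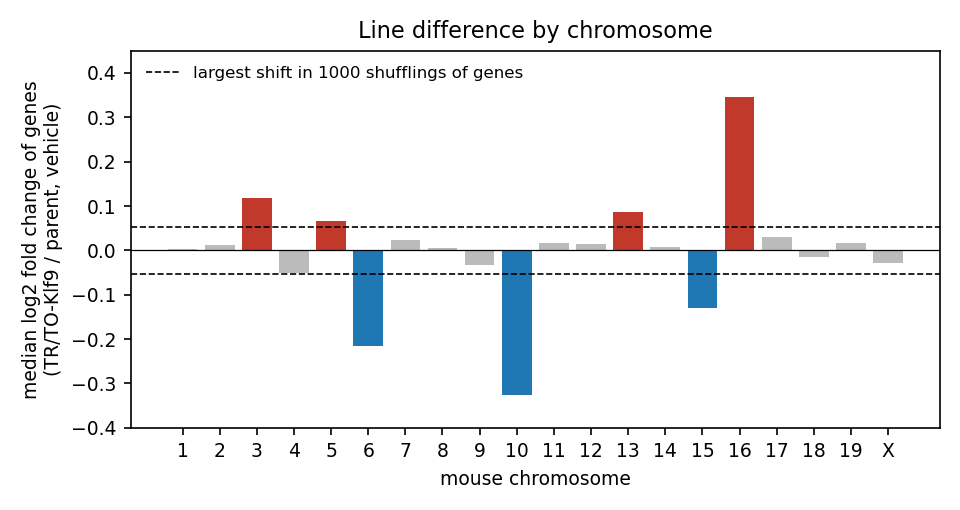
Median log2 fold change of the genes on each mouse chromosome (x axis) between TR/TO-Klf9 and parent vehicle cells (y axis); bars are medians and dashed lines mark the largest absolute chromosome median in 1000 shufflings of genes over the genome, 0.053. Chromosomes 16 and 10 lie farthest from 0, at 0.35 and −0.33.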

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

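In this part, the tests of transcript length, of vehicle against vehicle and of Klf9 in the identical library were chosen after the results were seen; the position of that library over other genes was predicted beforehand.

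The doxycycline response differed between the lines by a test of the difference itself for 1309 genes. The largest differences on the log2 scale, TR/TO-Klf9 minus parent, were 1.198 for Sat2, 1.14 for Klf9, 1.11 for Tmem255a, 1.06 for Nkx6-2, 1.03 for Enpp3, 1.02 for Borcs5, 0.97 for Ankrd37, 0.96 for Pxmp4, 0.91 for Zfp937 and 0.90 for Syce2. Downward they were −5.30 for Xkr5, −1.90 for Zbed6, −1.83 for Gpr161, −1.77 for Celf3, −1.75 for Pde6b, −1.70 for Zfp369, −1.65 for Trim56, −1.58 for Ceacam2, −1.49 for Cbl and −1.47 for Wdfy2. The Xkr5 value rests on no read in the doxycycline library against 0.38 CPM under vehicle and depends on the prior count of the fit. For Ceacam2, the parent line contributed 0.58 ± 0.16 (SE) in the opposite direction.

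Genes that fell after doxycycline in the TR/TO-Klf9 line tended to have long transcripts: across genes, rho of the log ratio with length was −0.37 and −0.51 against the 2 vehicle libraries, −0.16 between these, and −0.06 to −0.02 for the parent doxycycline libraries against parent vehicle 3, the only parent pairs examined. With the trend removed, 1146 of 2410 called genes kept call and direction. That met the mark against a length trend as the whole cause, over 1000, which was set after the counts were seen. The mark set for it was also met, as the vehicle libraries gave 1363 genes at that setting. This number does not measure length, being 1356 before. The 2 marks therefore do not decide for the called genes as a set. Zbed6 went from −1.83 to −1.71 and Celf3 from −1.86 to −1.89, and for these 2 genes length as the whole cause is argued against. Other falls shrank more, such as Map1b from −0.80 to −0.43 and Syne2 from −0.93 to −0.38. Differences between libraries of this line unrelated to doxycycline stay open for the kept calls too. The 2 vehicle libraries gave 1356 called genes against each other, and 1 doxycycline library cannot separate its own deviation from the treatment. That fit gave each TR/TO-Klf9 library its own group, with the spread from parent libraries only, so 1356 cannot be set directly against 2410. In it the median absolute log2 ratio above 8 CPM was 0.111 between the vehicle libraries. It was 0.171 and 0.162 for the doxycycline library against vehicle 1 and vehicle 2. Falls outnumbered rises at 1.5-fold against each vehicle library, but both comparisons use the same doxycycline library. The 2 vehicle libraries were lopsided too, with many more genes higher than lower at 1.5-fold in vehicle 1. Such an imbalance cannot separate repression from the deviation of 1 library, and repression following Klf9 induction remains a hypothesis on these data.

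The library listed both as TR/TO-Klf9 vehicle 3 and as doxycycline 1 may belong to either group. A doxycycline library with Klf9 induced as in the other one is argued against by its 45.91 CPM of Klf9, between the 43.91 and 48.53 of the vehicle libraries and far from 102.42. Over the 2410 called genes its median position between the vehicle mean (0) and the doxycycline library (1) was 0.164 (quartiles 0.01 and 0.34), and over the 68 genes called in all 3 fits it was 0.101, with none nearer to doxycycline. These genes were called for the distance of the other doxycycline library from vehicle. A second doxycycline library would therefore also tend to lie under 1 on them. Among libraries of this line, the counts of the identical library lay nearest to vehicle 2 (chi-square per degree of freedom 1.906). They lay farther from vehicle 1 (7.167) and farthest from the doxycycline library (10.104). A vehicle library and a doxycycline library without induction cannot be told apart, since both predict these values.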

How the results depend on the processing

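The alternatives that keep the identical library, remove the length trend, sum rows or combine choices were added after the data were seen; the others were planned, and the cause of a change was not tested unless stated. For doxycycline in the TR/TO-Klf9 line (2410 genes), DESeq2 gave 1319, only the groups compared 73, the identical library under both labels 0 or as doxycycline 0, the length trend removed 1483, both only the groups compared and the length trend removed 19, and only this line with the identical library as vehicle 379; fewer samples leave these within-line fits little power. Leaving out 1 library gave 1890 to 3800. Leaving out the only TR/TO-Klf9 doxycycline library ends this comparison. For the difference between lines (1309), DESeq2 gave 716, the identical library under both labels 0 or as doxycycline 0, the length trend removed 586 and leaving out 1 library 571 to 2910. With limma-voom, RLE, either filter, summed rows or the identical library as vehicle, both counts stayed within 1.5 times. Parent doxycycline gave 0 genes in every fit, and the line difference 3850 to 6083. In the parent line, samples with the same replicate number deviated with correlations of −0.048, 0.008 and 0.020, which gave no sign of pairing there. Only the parent line was checked, so pairing in the TR/TO-Klf9 line stays open. With the replicate block, 1381 genes passed for the TR/TO-Klf9 line, 607 for the difference, 0 for the parent line and 4670 for the line difference. Both G2/M lists then lost their call by camera (adjusted p of 0.110 in TR/TO-Klf9 and 0.0506 between lines). A block within lines gave 2953, 1920 and 0 for the first 3. Clock turned from −0.22 to 0.0865 and Itpr2 from −0.32 to 0.0409 with the length trend removed (0.0895 and 0.0465 with only the groups compared as well). Lists passing by camera (5, 4, 4 and 5 for TR/TO-Klf9, parent, difference and lines) numbered 0, 0, 0 and 1 with an estimated correlation. Calls were also lost where the estimate was under the preset, so that setting changes more than the correlation. The fry test gave 7, 0, 6 and 15, of which 3, 0, 3 and 5 had passed by camera. No filter on low counts gave 1 for the parent line. For the lines it gave 5, 1 up and 4 down against 2 up and 3 down before, with 4 shared. The length trend removed gave 2 for the difference. Depth limits genes under about 1 CPM, where the stricter filter leaves 12470 genes.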

Other observations

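In this part, the vehicle library and splits of parent samples were examined after the results were seen, and the tests of neighbouring genes were predicted beforehand.

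TR/TO-Klf9 vehicle 1 stood apart from every other library in stress genes, which were chosen after their values were seen. The inducible chaperone gene Hspa1b stood at 104.7 CPM there and at 10.3 in vehicle 2, 11.5 in the doxycycline library and 8.0 to 10.6 in the parent libraries. The heme oxygenase gene Hmox1 stood at 230 against 55.9 in vehicle 2 and 56.7 to 63.1 in the parent libraries, the metallothionein gene Mt2 at 78.3 against 18.2, Zfand2a at 286.2 against 89.6, and the cystine transporter gene Slc7a11 at 75.6 against 29.3. Of 28 oxidative stress and NRF2 genes, 19 were higher in vehicle 1 than in vehicle 2 and none lower (median log2 0.40), and of 18 heat shock and chaperone genes 12 were higher and none lower (median 0.55). Of 32 lysosome and autophagy genes 9 were higher and none lower. The comparison is between 2 libraries, and it sets the spread of this group in the 3 comparisons that use it.

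Genes that differ between the lines lay next to each other. The log2 fold changes of neighbours that do not overlap correlated at 0.2115 across genes (10135 pairs), and those of genes 20 places apart still at 0.1319, above the highest of 1000 shufflings (0.036 and 0.0291). Chromosome medians reached 0.35 on chromosome 16, −0.33 on 10, −0.22 on 6, −0.13 on 15 and 0.12 on 3, while the largest in shufflings was 0.053. In the parent doxycycline comparison the corresponding correlations were 0.02 and 0.01, and in the TR/TO-Klf9 one 0.04 and −0.001. Both explanations tested met their predictions. Chromosome segments gained or lost in 1 line may account for the long blocks, and sharing between adjacent genes may add to the excess at direct neighbours. At 5 and 50 places apart the correlations were 0.1522 and 0.1067. Segments with ends would also give such a decline, so the excess at direct neighbours cannot single out sharing. DNA copy number was not measured here, and the transfection and selection of the derivative line stay open as untested.

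In the parent line, all 10 splits of the 6 libraries gave 0 genes, the real one included (highest other 0), and 10 splits are too few for a share under 0.05. Parent pairs within a group differed by 0.952 to 1.569 in chi-square per degree of freedom without vehicle 1, and parent pairs with vehicle 1 by 3.818 to 6.516, against 8.326 for the TR/TO-Klf9 vehicle pair. Parent libraries gave 4 of the 5 residual degrees of freedom, so p-values of the lone doxycycline library rest mostly on their spread, and the sources used here do not say whether duplicate reads were removed. The deepest parent library, vehicle 1, differed from vehicle 2 in a way that followed counts per base, with a median log2 ratio of 0.13 in the lowest group of genes and −0.20 in the highest.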
